A study of Mus musculus with 2 samples.

How the data were processed

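Libraries were made from E13.5 mouse hearts, 1 from wild-type and 1 from Lmna H222P/H222P hearts. RNA was extracted with a Zymo Research kit, per the labels, which give total RNA as the molecule; how RNA was selected for the libraries is not given in the sources used here. Groups were taken from the genotype label. The deposited values are raw counts of reads per gene, whole numbers that were not normalized. The submitters' processing notes name STAR, HTSeq and DESeq and the mouse genome build mm10, without versions or roles; the annotation release behind the gene symbols is not given in the sources used here. Each deposited table holds 3 columns of counts (both strands together and each strand alone) and 4 summary entries for unmapped, multiply mapped, unassigned and ambiguous reads, the layout STAR writes. Reads mapped to several places are not in the gene counts, so genes with near-identical copies are undercounted.

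The column of reads from the reverse strand held 19.3 times (wild type) and 20.5 times (H222P) the reads of the other strand column and was used throughout, by a rule that required a 3-fold excess. Reads assigned to genes were 82.8% of 39445195 reads in the wild-type library and 82.0% of 30641442 in the H222P library. The summary entries were left out of library sizes. Unmapped reads were 5.40% and 5.10%, reads mapped to several places 5.37% and 6.09%, reads outside genes 3.88% and 4.45%, and ambiguous reads 2.53% and 2.38%. At these depths 3 reads correspond to 0.097 CPM in the wild-type library and 0.113 CPM in the H222P library, the floor used for a gene with 0 reads.

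Of 55348 gene entries, 53238 matched 1 symbol of GENCODE mouse release M21 (GRCm38, the same assembly as mm10) and 113 matched several. A further 996 took a biotype from RefSeq only and 1001 matched none. Coordinates and biotypes come from release M21. Mitochondrially encoded genes were not analysed here: no entry bore the name of one. The 13 mitochondrial messenger RNAs were compared with the nuclear transcripts of release M21 by blastn 2.17.0, and 16 entries with at least 90% identity over at least 100 bases are described as mitochondrial-like.

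Scaling used TMM factors from edgeR 4.0.16 in R 4.3.3 (0.948 for wild type, 1.05 for H222P). The log2 ratio of each gene, Lmna H222P/H222P over wild type, used a prior count of 0.5 in each library. Its 95% interval is the exact Clopper-Pearson interval of the binomial share of reads given their sum, computed in Python 3.11.15 with scipy 1.17.1. It covers counting error only and leaves out variation between hearts. Reads without molecular identifiers are not independent molecules, so the interval can be too narrow even for counting error. With 1 library per group no test of the genotypes could be run, so genes were described by size: a mean of at least 1 CPM and a ratio of at least 2-fold. The text also names, by rule, Lmna, Kdm1a and 9 textbook heart genes, then the 12 highest and 12 lowest protein-coding genes with a mean of at least 5 CPM, ranked by the interval bound nearest to a ratio of 1. Globin, sex-linked and mitochondrial genes were kept out of that ranking, and 1 gene it gave is not reported here. In each list the most abundant member, the highest, the lowest and the next by size with a mean of at least 5 CPM could be named.

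Gene lists (50) for pathways, cell types and other tissues, the rule for named genes, the scaling and 11 alternatives were fixed before the data were examined. For each list the members at least 1.5-fold higher, lower and between were counted. The median log2 ratio was placed among the medians of 10000 random lists of the same size drawn from 20 bins of mean CPM, and a list outside the central 95% was said to stand apart. This describes the 2 libraries and is not a test of the genotypes. The list of mitochondrially encoded genes had no entry, and that of small nucleolar and spliceosomal RNAs had too few measured members for a percentile, which left 48.

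The steps were tested on simulated counts for this comparison (14716 genes, 200 of them changed). Both libraries were drawn with counting error alone around a shared level per gene, without variation between hearts or joint changes of genes. The simulation therefore checks the computation, and does not show how often real genes or lists would pass. All 50 genes at each of the log2 changes 1.5, −1.5, 3 and −3 passed the 2-fold rule, as did 6 of 14516 unchanged genes, and 95.3% of intervals held the true ratio. Of 20 simulated lists shifted by 0.5, 20 lay above the central range, and 2 of 20 unshifted lists lay outside it. The alternatives were DESeq2 1.42.0 size factors, total counts, no filter, a filter at 5 CPM, a prior count of 5, the unstranded column, protein-coding genes only, exclusion of globin genes, thinning of the deeper library, list members of 1 list only and means in place of medians. Exclusion of the globin genes together with the mitochondrial-like entries, and exclusion of the other-tissue list members, were added after the data were seen; the mitochondrial-like entries were not left out alone.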

Results

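RNA was measured in embryonic mouse hearts collected at E13.5, a stage of mid-gestation when the chambers have formed and the ventricular wall is still maturing. The series held 2 RNA-seq libraries, described in the labels as total RNA, 1 from wild-type hearts and 1 from hearts homozygous for the H222P mutation of Lmna, the gene of the nuclear lamina proteins lamin A and lamin C. H222P is a missense mutation used in mice to model the heart and muscle disease caused by LMNA mutations. The labels gave strain 129sv for both libraries and did not say how many hearts, or hearts of which sex, went into each. Reads assigned to genes numbered 32669225 in the wild-type library and 25120790 in the Lmna H222P/H222P library, and 24798 and 24747 genes had at least 1 read. With 1 library per genotype, every difference given here lies between these 2 libraries, has no replicate check and carries no p-value. The 95% intervals cover counting error only.

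The comparison asked how the transcriptome of the mutant heart differs from that of the wild-type heart at this stage, in a study concerned with the histone demethylase LSD1. Genes of the contractile apparatus were lower in the H222P library: 30 of 36 measured sarcomere genes were at least 1.5-fold lower and 0 were at least 1.5-fold higher. Genes of oxidative phosphorylation, fatty acid oxidation, fibrillar matrix and endothelium were also lower as groups. Genes of DNA replication and ribosome biogenesis were higher as groups (medians 0.36 and 0.47), with 4 of 35 and 8 of 31 at least 1.5-fold higher. Transcripts of hepatocytes and of red cell precursors were far higher, with all 22 measured liver genes at least 1.5-fold above the wild-type library and a median log2 ratio of 7.49.

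Of 14716 genes with a mean CPM, the read count scaled to library size, of at least 1, 876 were at least 2-fold higher in the H222P library and 640 at least 2-fold lower. For 596 and 346 of them the whole 95% interval lay beyond 2-fold. Protein-coding genes made up 802 of the higher and 539 of the lower genes. At a mean of at least 5 CPM, 394 genes were higher and 333 lower. The higher genes included 53 members of the lists written for other tissues. Of the higher genes, 373 had less than 1 CPM in the wild-type library, and of the lower genes, 160 had less than 1 CPM in the H222P library. Among genes with at least 5 CPM in the wild-type library, a bound that favours lower genes, 187 were higher and 399 lower. The median log2 ratio over all measured genes was −0.01. Higher genes were 57.8% of those at least 2-fold apart, against 70.6% (1076 higher, 449 lower) when libraries were scaled by total counts alone, which moved the median to 0.15.

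**Figure D1:**
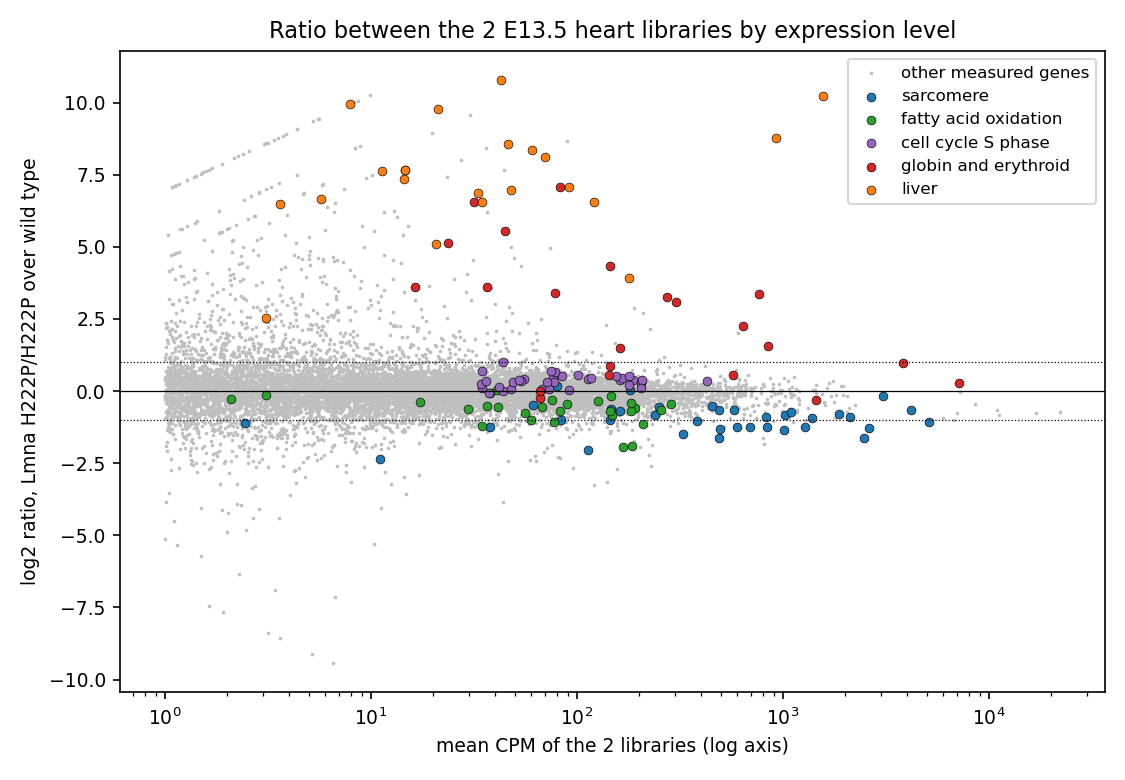
Log2 ratio of Lmna H222P/H222P over wild type (y axis) against the mean CPM of the 2 libraries (x axis, log scale), 1 point per measured gene, with 5 gene groups coloured and dotted lines at 2-fold. Liver genes (orange) lie far above 0 at a median of 7.49, and sarcomere genes (blue) lie mostly below 0 at a median of −0.96.

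Lmna itself (chromosome 3, 88480147 to 88509956, mm10) had 2068 reads in the wild-type library and 1865 in the H222P library, a log2 ratio of 0.08 (95% interval −0.01 to 0.17). A missense mutation need not alter the amount of transcript, so this value does not check the labels. Kdm1a, which encodes LSD1 (chromosome 4, 136550540 to 136602723), had 3628 and 3549 reads, a log2 ratio of 0.19 (0.13 to 0.26). Among 26 nuclear envelope and lamina genes, 1 was at least 1.5-fold higher, 2 were lower and 23 lay between. Lbr, the lamin B receptor, was 1.52-fold higher (1.46 to 1.60), and the muscle-enriched lamin-interacting gene Mlip was 2.15-fold lower (2.02 to 2.29). In the list of LSD1 complex members and histone demethylases, 27 of 29 genes lay within 1.5-fold and 2 were higher. Kdm7a was 1.60-fold higher (1.47 to 1.74). The other had a log2 ratio of 3.94, at a mean under the 5 CPM needed for naming a gene. The list median of 0.11 on the log2 scale stood at percentile 97.1 of random lists matched for expression. Without a filter on low counts it stood at 98.8 (median 0.13). Polycomb and Trithorax genes had a median of 0.17 (percentile 99.7, and 82.3 for the mean of 0.12) with 30 of 31 members within 1.5-fold, and Epop was 2.15-fold higher (1.74 to 2.68). All of these genes were measured in a library that also held more liver and erythroid transcripts (list medians 7.49 and 2.67).

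The 12 protein-coding genes that stood highest in the H222P library were Alb, Ambp, Afp, Kng1, Serpina6, Fga, Fgg, Fgb, Apoa1, Serpind1, Ugt2b34 and Spp2, most of them genes of secreted plasma proteins made by the liver. Alb, serum albumin (chromosome 5, 90460897 to 90476602), had 81 reads in the wild-type library and 83174 in the H222P library, a log2 ratio of 10.22 (9.92 to 10.56). Afp, alpha-fetoprotein, had 130 and 48905 reads, a log2 ratio of 8.78 (8.53 to 9.04). The fibrinogen chains Fgg and Fgb had log2 ratios of 8.57 (7.62 to 9.99) and 8.34 (7.56 to 9.41), and Apoa1, the main protein of high-density lipoprotein, 8.13 (7.45 to 9.01). Ambp, Kng1, Fga and Ugt2b34 rested on 1 or 2 wild-type reads, and the ratio of Ambp was 10.78 on the log2 scale with an interval of 8.89 to 16.67. Spp2 had 0 reads in the wild-type library and 523 in the H222P library, at least 204-fold higher against a floor of 3 reads.

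The 12 lowest included Gm14326, Gm14325, Gm10260, Fabp4, Ckm, Rpl29, Aspn, Sln, Adh1, Mgp and Casq2. Fabp4, a fatty acid-binding protein of capillary endothelium and fat cells (chromosome 3, 10204088 to 10208576), was 14.5-fold lower (12.4 to 17.3). Genes of striated muscle were among them. Ckm, muscle creatine kinase (chromosome 7, 19404776 to 19422841), was 9.55-fold lower (8.79 to 10.4), sarcolipin (Sln) 7.89-fold lower (log2 interval −3.33 to −2.67) and the calcium-storage gene Casq2 6.44-fold lower (6.05 to 6.86). The matrix genes Aspn and Mgp were 9.44-fold (7.34 to 12.5) and 7.26-fold lower (6.40 to 8.29), and the alcohol dehydrogenase gene Adh1 7.56-fold lower (6.20 to 9.38). Gm14326 had 322 wild-type reads and 0 in the H222P library, at least 91.8-fold lower against a floor of 3 reads, and Gm14325 had 412 and 2 reads, a log2 ratio of −7.14 (−10.51 to −5.60). Both are zinc finger genes of distal chromosome 2 with near-identical neighbours, and lie in a run of 8 measured genes between 176708328 and 178034022, picked out after the values were seen, that together had 1783 wild-type and 17 H222P reads. Rpl29 (8.99-fold lower, 8.34 to 9.71) and the ribosomal protein-like Gm10260 have near-identical copies elsewhere, and Gm10260 moved from a log2 ratio of −5.30 to 0.22 when reads of both strands were counted, so these 4 ratios are uncertain.

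Sarcomere genes had a median log2 ratio of −0.96, below the 2.5th percentile of matched random lists. Myh7, the slow myosin heavy chain that dominates the fetal ventricle, was 2.10-fold lower (2.09 to 2.12), while Myh6, the chain that dominates the atria, was 1.13-fold lower (1.12 to 1.14). Myom2, of the sarcomere M-band, was 5.18-fold lower (4.18 to 6.54) and Myoz2, of the Z-disc, 4.14-fold lower (3.89 to 4.41), whereas Pdlim3 had a log2 ratio of 0.18. Of 16 ventricular markers, 12 were at least 1.5-fold lower and 1 was higher (median −1.07), with phospholamban (Pln) 3.10-fold lower (3.04 to 3.17) and Hand1 1.85-fold higher (1.61 to 2.14). Of 19 atrial markers, 8 were lower and 1 was higher (median −0.33), with Myl4 1.88-fold lower (1.86 to 1.90) and Nr2f1 1.54-fold higher (1.44 to 1.66). The atrial list stood at percentile 0.32, but at 11.99 (median −0.20) without members that other lists share. The natriuretic peptide genes Nppa and Nppb, markers of trabecular myocardium at this stage, were 2.31-fold (2.26 to 2.36) and 2.19-fold lower (2.07 to 2.31). The trabecular list had 7 of 16 members lower and 0 higher (median −0.43), and the compact myocardium list 4 of 13 lower and 0 higher (median −0.20, percentile 9.6, but −0.35 at percentile 0.75 without the filter on low counts).

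In the calcium handling and ion channel list, 20 of 38 genes were at least 1.5-fold lower and 0 were higher (median −0.59). Atp2a2, the calcium pump of the sarcoplasmic reticulum, was 1.52-fold lower (1.5 to 1.54). Cardiac transcription factors had a median of −0.38, with 9 of 29 lower, 3 higher and 17 between. Hopx was 2.58-fold lower (2.46 to 2.72), Ankrd1 2.37-fold lower (2.32 to 2.42) and Nkx2-5 1.39-fold lower (1.31 to 1.46), while Tbx5 had a log2 ratio of −0.13 that became positive with total-count scaling. Isl1, a factor of cardiac progenitors and of some neurons, was 4.78-fold higher (4.0 to 5.77). In the same library the liver list made up 0.700% of reads on genes (exact binomial interval 0.697 to 0.704), against 0.0037% in the wild-type library (0.0035 to 0.0039), and globin genes 1.85% against 1.12%.

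**Figure D2:**
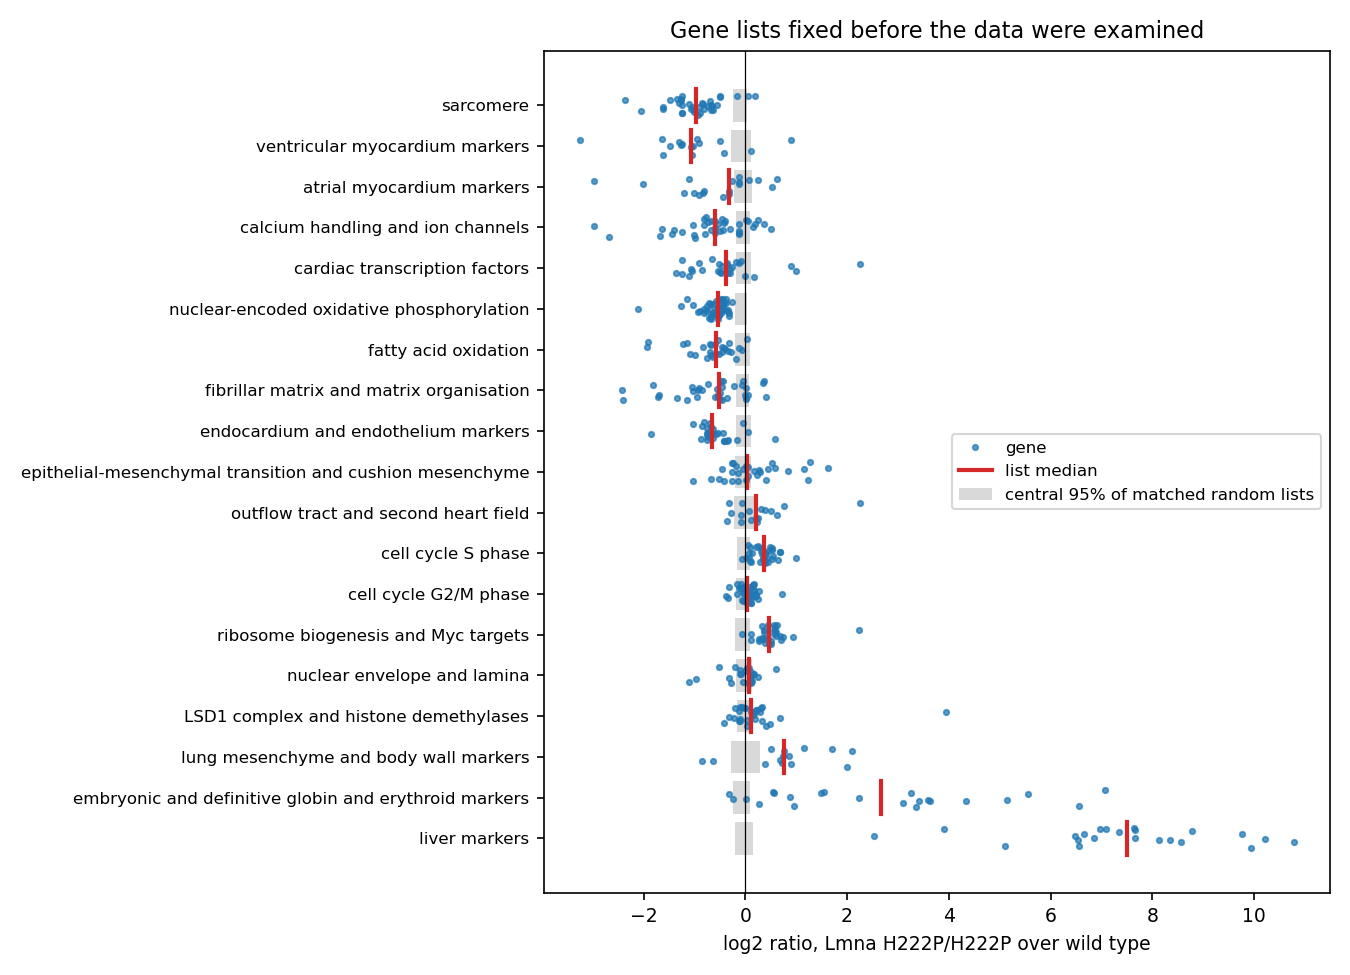
Log2 ratio of Lmna H222P/H222P over wild type (x axis) for the measured members (points) of 19 gene lists, with list medians (red lines) and the central 95% of medians of 10000 expression-matched random lists (grey bars). The medians run from −1.07 for ventricular markers to 7.49 for liver markers.

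Energy metabolism genes were lower in the H222P library. All 47 nuclear-encoded oxidative phosphorylation genes had log2 ratios below 0 (−2.11 to −0.25, median −0.55), and 20 were at least 1.5-fold lower. Atp5b, the catalytic beta subunit of ATP synthase, was 1.39-fold lower (1.38 to 1.41), and the muscle forms Cox8b and Cox7a1 were 4.30-fold (3.42 to 5.53) and 2.40-fold lower (2.07 to 2.80). Of 28 fatty acid oxidation genes, 14 were lower and 0 were higher (median −0.58). The fatty acid transporter Cd36 was 3.82-fold lower (3.63 to 4.02) and Fabp3, the heart fatty acid-binding protein, 3.79-fold lower (3.61 to 3.97), while Cpt2 had a log2 ratio of 0.03 (−0.09 to 0.15). Glycolysis genes had a median of −0.38 with 6 of 21 lower and 0 higher. Ldhb was 2.13-fold lower (2.07 to 2.20), and the glucose transporter Slc2a1 had a log2 ratio of 0.30. A set of 16 nuclear pseudogene entries whose sequence resembles mitochondrial messenger RNAs held 10.5% of wild-type and 6.81% of H222P reads on genes, a log2 ratio of −0.79 for their sum. Each shares at least 90% identity over at least 100 bases with a mitochondrial messenger RNA. Liver and erythroid transcripts were higher in the same library (list medians 7.49 and 2.67).

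Extracellular matrix genes were lower, with 15 of 36 fibrillar matrix genes at least 1.5-fold lower and 0 higher (median −0.52). Ogn and Thbs2 were 5.38-fold (4.91 to 5.91) and 5.27-fold lower (4.80 to 5.81), Col1a1 3.54-fold lower (3.46 to 3.62) and Col3a1 1.89-fold lower (1.85 to 1.92). Basement membrane genes had 6 of 17 members lower and 1 higher (median −0.50), with Lama2 1.87-fold lower (1.76 to 1.99) and Lama1 1.95-fold higher (1.71 to 2.24). Endocardial and endothelial markers had 16 of 27 lower and 1 higher (median −0.64), with the caveolar gene Cav1 3.62-fold lower (3.47 to 3.78) and Vwf 1.5-fold higher (1.39 to 1.63). Epicardial markers split evenly, 5 lower and 5 higher of 21, with a median of −0.36 but a mean of 0.04. Msln was 7.04-fold lower (5.58 to 9.09) and complement C3, also made by liver, 16.6-fold higher (13.6 to 20.6). Valve and fibroblast markers had 8 of 22 lower and 6 higher, a median of 0.32 and a mean of −0.18, with Pdgfra 2.40-fold higher (2.28 to 2.52). Smooth muscle and pericyte markers had 4 of 18 lower and 4 higher (median −0.24, percentile 2.3, and 37.5 for the mean), with Cspg4 1.66-fold lower (1.54 to 1.80). These groups, too, were measured in a library with higher liver and erythroid transcripts (medians 7.49 and 2.67).

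Genes of epithelial-mesenchymal transition and cushion mesenchyme lay mostly between the bounds (23 of 30), with 5 higher and 2 lower and a median of 0.03, at percentile 83.2. Twist1 was 2.33-fold higher (2.04 to 2.67), Has2, the hyaluronan synthase of the cushions, 2.43-fold higher (2.09 to 2.83) and Snai1 1.43-fold higher (1.17 to 1.77). Snai2 had a log2 ratio of −0.04 (−0.20 to 0.11), and Postn, a matrix gene of valve mesenchyme, was 2.03-fold lower (1.98 to 2.09). Outflow tract and second heart field genes had 3 of 17 higher and 0 lower (median 0.21, percentile 98.7), and the median was 0.12 (percentile 87.5) without members of the other-tissue lists. TGF-beta and BMP genes had 6 of 30 lower and 2 higher (median −0.28, and a mean of −0.21 at percentile 3.3), with the trabecular growth factor Bmp10 2.17-fold lower (1.97 to 2.38) and Tgfbi 2.15-fold higher (2.00 to 2.32). Wnt targets had 7 of 20 higher and 1 lower (median 0.24, percentile 97.7, and 83.3 at a mean of at least 5 CPM), with Lef1 1.78-fold higher (1.51 to 2.11). Notch pathway genes (4 of 18 lower, 1 higher) and ERK feedback targets (3 of 18 higher, 1 lower) did not stand apart, at percentiles 10.7 and 87.7. Hey2, a Notch target of the ventricle, was 1.87-fold lower (1.77 to 1.99). Markers of liver, red cells, lung mesenchyme and neural tissue were higher in the same library (list medians 7.49, 2.67, 0.75 and 0.81).

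DNA replication genes were higher as a group: the S phase list had a median of 0.36, above the central 95% of random lists, with 4 of 35 at least 1.5-fold higher and 0 lower. Ccne1, cyclin E1, was 2.01-fold higher (1.85 to 2.18) and the replication-licensing gene Cdc6 1.60-fold higher (1.46 to 1.76). The G2/M list stood at percentile 95.2 (median 0.04) with 39 of 40 genes within 1.5-fold, and Mki67, the proliferation marker Ki-67, was 1.65-fold higher (1.61 to 1.68). Ribosome biogenesis genes and Myc targets had 8 of 31 higher and 0 lower (median 0.47), with Myc 1.92-fold higher (1.72 to 2.14) and Npm1 1.27-fold higher (1.25 to 1.29). The highest member, the transferrin receptor gene Tfrc (4.73-fold, 4.61 to 4.86), is also strongly expressed in red cell precursors, whose markers were higher in the same library (median 2.67). All 45 cytoplasmic ribosomal protein genes of the list lay within 1.5-fold. Stress response genes of the integrated stress and unfolded protein responses had 4 of 27 higher and 1 lower (median 0.25), with the amino acid synthesis genes Asns 4.0-fold higher (3.66 to 4.37) and Phgdh 2.07-fold higher (1.96 to 2.19), and the lipoprotein receptor gene Vldlr 2.81-fold lower (2.64 to 2.99). Heat shock genes had a median of 0.11 (percentile 98.5) with 17 of 20 within 1.5-fold, and the mean of 0.12 stood at percentile 87.1. The growth and stress lists were all measured in the library with higher liver and erythroid transcripts (list medians 7.49 and 2.67). How much RNA of such cells adds to these values was not tested.

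Erythroid genes were higher in the H222P library, 16 of 22 by at least 1.5-fold and 0 lower, with a median of 2.67. Hemgn and Klf1, genes of nucleated red cell precursors, had log2 ratios of 7.08 (6.63 to 7.60) and 6.56 (5.97 to 7.31), while the abundant embryonic globin Hbb-y was 1.20-fold higher (1.20 to 1.21) and Hba-a1 1.25-fold lower (1.23 to 1.27). Among liver markers, transferrin (Trf) was 15.0-fold higher (13.9 to 16.2), and Fabp1 with 0 and 418 reads was at least 163-fold higher; with Fabp1 at that bound the liver median was 7.35. Lung mesenchyme and body wall markers had 10 of 14 higher and 2 lower (median 0.75), with Foxf1 4.0-fold higher (3.60 to 4.46) and Tbx4 1.80-fold lower (1.52 to 2.14). Neural crest, Schwann and neuronal markers had 11 of 20 higher and 1 lower (median 0.81), with Tubb3 3.98-fold higher (3.17 to 5.10) and Ednrb 1.66-fold lower (1.59 to 1.73). Lung epithelium markers had 3 of 18 lower and 1 higher, with Nkx2-1 2.02-fold lower (1.68 to 2.45). Macrophage and leukocyte markers had 4 of 22 higher and 3 lower, and the platelet gene Pf4 was 8.89-fold higher (7.65 to 10.4). Skeletal muscle markers had 3 of 10 higher and 2 lower, and thymus and pharyngeal markers 1 of 6 lower and 0 higher; both lists stood above random lists only without a filter (percentiles 99.7 and 97.8).

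Both libraries held transcripts of Xist, made by the inactive X chromosome of females, and of the Y chromosome. Xist had 12116 wild-type and 1727 H222P reads, 6.0-fold lower (5.70 to 6.31), while Ddx3y was 2.99-fold higher (2.80 to 3.19) and Eif2s3y 3.14-fold higher (2.88 to 3.44). Genes on the X or Y chromosome made up 55 of the 1516 genes at least 2-fold apart. Among 26 imprinted genes, 5 were at least 1.5-fold higher and 1 was lower, with Peg10 3.15-fold higher (3.0 to 3.31) and Dcn 3.29-fold lower (3.15 to 3.45). Long nuclear RNAs (3 of 15 higher, 1 lower) and histone genes (1 of 7 lower, 0 higher) did not stand apart, and all 3 measured small nucleolar or spliceosomal RNA genes lay within 1.5-fold. Of 8 strain-variable or pseudogene-prone genes, 2 were lower and 1 was higher, with a median of −0.52 and a mean of 0.42. The higher one, Hc, encodes complement C5, a liver product (4 and 321 reads). Lists of p53 targets (4 of 26 lower, 0 higher), immediate-early genes (2 of 21 lower, 0 higher), hypoxia targets (1 of 27 lower, 0 higher) and interferon-stimulated genes (7 of 25 lower, 2 higher) did not stand apart at this filter. The interferon list did so without a filter and at a mean of at least 5 CPM (median −0.27 in both, percentiles 0.40 and 2.3). In total 13 of 48 lists stood above the central 95% of random lists and 16 below it. For lists whose members vary independently, as in the random lists, 2.4 would lie outside. Members of a real list can change together between 2 libraries, so the excess over 2.4 does not measure chance. With means in place of medians 18 lists stood apart, and the TGF-beta and BMP, stress response and lung mesenchyme lists were among those that no longer did.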

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

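No test in this part was chosen after the result was seen. Each share was compared by its exact binomial interval, and only shares above the wild-type level were flagged. At these depths the intervals are so narrow that almost any difference passes. Reads mapped to several places were 6.09% of all reads in the H222P library against 5.37% in the wild-type library, a share in data that the gene comparison does not use and above the wild-type level. Reads outside annotated genes were 4.45% against 3.88%, likewise above the wild-type level. Unmapped reads (5.10% against 5.40%) and ambiguous reads (2.38% against 2.53%) were below the wild-type level, also with intervals apart. With 1 library per group none of these differences has a replicate check.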

How the results depend on the processing

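Of the 13 alternatives, the exclusion of globin genes together with mitochondrial-like entries and the exclusion of other-tissue list members were chosen after the results were seen. No paired analysis was possible because each group has 1 library. Of 609 list values under an alternative, 577 kept their call, and 29 of 48 lists kept it under all alternatives run for them. The sarcomere, ventricular, oxidative phosphorylation, fatty acid oxidation, S phase, liver and erythroid lists were among these 29. Of 1192 single-gene values, 154 moved beyond their counting interval, 119 of them with total counts, and 1 of those at least 2-fold apart changed sign: Gm10260, to 0.2193 with the unstranded column. Total counts moved the median of all genes to 0.145.

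Without a filter 8784 genes were at least 2-fold apart (4746 higher, 4038 lower), and at 5 CPM 727 (394 and 333); the filter sets how many genes are compared. Without a filter, lists that newly stood apart were compact myocardium (−0.3477), interferon (−0.2747), LSD1 (0.1259), skeletal muscle (0.9056) and thymus (0.3244). At 5 CPM interferon (−0.2747) and lung epithelium (−0.3680) newly stood apart and Wnt (0.1028) no longer did. Smooth muscle was lost with a prior of 5 (−0.2260) and after thinning (−0.2295). Wnt was lost with the unstranded column (0.1392) and with protein-coding genes (0.2434). LSD1 was gained with protein-coding genes (0.1068) and after thinning (0.1106). Without other-tissue members the outflow list was lost (0.1157). With members of 1 list only, atrial (−0.1983), outflow (0.2132), Wnt (0.2434) and heat shock (0.1055) were lost.

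With means, 18 lists stood apart. Those lost with their sign kept were outflow (0.2668), TGF-beta (−0.2112), Wnt (0.3541), heat shock (0.1175), stress response (0.2714), Polycomb (0.1154), smooth muscle (−0.0642), lung mesenchyme (0.7901) and sex-linked genes (0.7158). Epicardium (0.0441), valve and fibroblast (−0.1795) and strain-variable genes (0.4211) changed sign and also no longer stood apart. Lung epithelium was gained (−0.4852). Apart from the filter, the cause was not tested. Depth limits genes near 0.1 CPM, where 3 reads set the floor.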

Other observations

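The tests in this part were chosen after the results were seen, except those on the further liver list and on the gut and pancreas list. Globin genes differed from each other in the H222P library. The embryonic globins Hbb-bh1 and Hba-x were 10.3-fold and 2.93-fold higher than in the wild-type library, but Hbb-y, also embryonic, only 1.20-fold. The adult Hbb-bs was 1.95-fold higher, and Hba-a1 had a log2 ratio of −0.32. The platelet genes Ppbp (158 and 2703 reads) and Pf4 (191 and 1454 reads) were also higher. Hmga2 and Lin28b, genes that are high in early embryonic tissue and decline with development, were 4.49-fold (log2 interval 2.10 to 2.23) and 4.13-fold higher (1.83 to 2.26). Barx1, a factor of stomach mesenchyme, had 8 and 1234 reads, Pitx1, a factor of hindlimb and other mesenchyme, 3 and 535, and the glucagon gene Gcg 0 and 278, at least 108-fold higher against a floor of 3 reads. These genes, apart from Hbb-y, Hba-a1 and Pf4, were chosen after their values were seen.

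Rps3a1 was 2.63-fold lower in the H222P library, with 22266 wild-type and 7239 H222P reads, while its near-identical copies Rps3a2 and Rps3a3 had log2 ratios of 0.38 and 0.92. The sum over the 3 entries had a log2 ratio of −0.34. Ccnb1ip1 had 17 and 477 reads, and the non-coding Gm42047 had 405 and 0, at least 115-fold lower against a floor of 3 reads. They too were chosen after their values were seen.

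Liver and erythroid transcripts were higher in the H222P library. More circulating blood alone is argued against by the fixed liver list, whose median log2 ratio of 7.49 belongs to genes that red cells do not express. Liver tissue carried over at dissection stays open: of a further 25 liver genes, listed before their values were seen, 14 were measured, only 5 of them at 1 CPM or more in the wild-type library, and 85.7% of the 14 (12 genes) were at least 4-fold higher. That share of measured genes met the prediction written beforehand for carried-over liver, but the filter favours such genes. Without the filter 17 of the 25 (68.0%, under the predicted share) were at least 4-fold higher (0 reads set to 3) and 0 were 2-fold lower. Alb and Afp stood at 3140 and 1846 CPM in the H222P library. Gut or pancreas tissue stays open, since of 19 listed genes 13 lay below the filter. Of the measured 6, 33.3% (2 genes) were at least 4-fold higher, against 4 of all 19 without the filter. Log2 ratios of the measured 6 ran from 0.86 to 5.2, with a median of 1.10. An effect of the genotype on the liver and erythroid transcripts was not tested.

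Contractile and metabolic muscle genes were lower in the same library. Dilution of heart RNA by other tissue would lower them alike and stays open: 66.7% of sarcomere genes (24 of 36) had their whole interval more than 0.2 from the list median on the log2 scale, but these intervals leave out the variation of a gene between hearts, so the value decides nothing. A smaller ventricular share alone would raise atrial markers, whose median lay at percentile 0.32, though at 11.99 without members shared with other lists. A less mature heart is a candidate explanation: muscle isoforms that appear later in development had a median 0.85 below that of early cardiac genes (a difference of −0.85, medians −1.44 and −0.59, 12 genes each), in lists put together after many values, that of Ckm among them, were known. Whether lower maturity would come from the genotype or from hearts of an earlier stage is not settled by 1 library per group.

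A block of zinc finger genes on distal chromosome 2 (176708328 to 178034022) was nearly silent in the H222P library. All 8 measured genes of the block, whose edges were set from these values, were at least 8-fold lower, 4 of them had 0 reads, and their sum was 1783 wild-type and 17 H222P reads. A tissue present in the wild-type library and missing from the other stays open: outside the block, only 1 protein-coding gene with at least 100 wild-type reads was at least 64-fold lower by its ratio, but 16 were at least 8-fold lower, and the 1 gene was Sftpc, a marker of lung epithelium (211 and 1 reads). A strain or haplotype difference near this block is a candidate explanation and cannot be told apart from an effect of the genotype or from reads shared among near-identical copies, with 1 library each and a block chosen for its values; 0.0% of 15 measured genes starting within 2 Mb of a window around it (176500000 to 178050000) were 8-fold lower. Of the zinc finger genes among those 15, Gm14399 had 211 and 173 reads, Gm14443 had 30 and 29, and Zfp931, next to the block, had 596 and 333, 1.53-fold lower.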
